A study of Sus scrofa with 6 samples.

How the data were processed

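Gene expression was measured with Affymetrix porcine expression arrays in 2 cell lines, OBGF400 and PK15, with 3 arrays per line. Per the labels' protocols, RNA from 9 independent cultures of each line was combined into 3 pools, the cells were untreated, both media held 10% bovine calf serum, and 8 µg of total RNA of each pool was labelled with biotin by a 3′ one-cycle method. The base medium differed between the lines, and the PK15 medium also held an antifungal agent. Medium, line and any batch of labelling or hybridization therefore cannot be told apart here. No scan dates were used here. Because a replicate is a pool of cultures of 1 line, each p-value measures the spread between pools, not between animals or lines.

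The deposited table gives 1 log2 signal per probe set and array. The submitters' processing notes name the package affy without a version. The background correction, summarisation and normalization are not given in the sources used here. The 6 columns had near-equal distributions, with means of 5.41 to 5.42, and shared a lower limit, called the floor here, of 2.13 on the log2 scale. Between 25.8% and 27.3% of the probe sets of an array lay at the array's minimum. The table used here holds no detection calls. A gene within 0.1 of the floor on all 3 arrays of a line is described as at the floor, and a difference against such a level depends on where the floor was set. Values at the floor have no order, so differences that involve it were not ranked against each other beyond the selection rule given below. Some probe sets gave 1 identical value above the floor on all 3 arrays of a line, such as those of BDNF, PDGFRB and TGFB2 in PK15 and of DDC in OBGF400. An SD of 0 there is no measure of precision. The number of arrays limits the precision. The median SD between arrays of a line was 0.24 for probe sets with a mean of 4 to 6 and 0.08 for those above 12.

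Of 24123 probe sets, 124 control probe sets were left out of the tests and 23999 were tested. Gene symbols came from the platform annotation table, in which 10069 tested probe sets had 1 symbol, 198 had several and 13732 had none, which leaves them unnamed here. Of the probe sets with 1 symbol, 9961 were found by Entrez number in the RefSeq gene table of the pig assembly Sscrofa11.1, which renamed 0 symbols. No coordinates are given, since no build is named for the array's probes in the sources used here. For the 6765 genes, the probe set with the highest mean over all 6 arrays stood for the gene. More than 1 probe set was present for 2261 genes, and 86 genes had called probe sets of opposite sign. For some named genes with several probe sets, such as LAPTM5, NPY, FST, MYH9 and MYH10, only 1 was called.

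The lines were compared with limma 3.58.1 (lmFit and eBayes, without trend or robust options, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05, once over probe sets and once over genes. Tables were prepared in Python 3.11.15. All differences are OBGF400 minus PK15 on the log2 scale. Gene lists were compared with the other genes by camera with its preset correlation of 0.01, for lists of at least 5 measured genes, with Benjamini-Hochberg adjustment over the 30 lists, and by fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. A called list or gene is one with an adjusted p under 0.05. The lists covered neural progenitors, forebrain patterning, neurons, axon guidance, astrocytes, oligodendrocytes, ensheathing and Schwann cells, neural crest, matrix, contractile genes, epithelium, kidney, HOX genes, endothelium, leukocytes, cell cycle, p53, interferon, MHC, cytokines, herpesvirus entry, neurotrophic factors, Notch, Wnt, TGF-beta, cholesterol, glycolysis, oxidative phosphorylation, ribosomal proteins and reference genes. A gene could belong to several lists.

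The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest and 12 smallest differences among called genes whose arrays did not overlap and which had a proper symbol, up to 3 called genes with the largest rise and 3 with the largest fall in each list, and a fixed set of markers. The alternatives were quantile normalization, median centring, 2 filters on dim probe sets (above the 25th percentile or above the median), a trended and robust variance, array weights, log2 of the linear value plus 32, the mean of a gene's probe sets, an adjusted p threshold of 0.01, the replicate number as a block, leaving out each array, and for lists an estimated correlation and ranks. After the data had been seen, 3 more were added: leaving out probe sets that vary by under 0.1, and scaling the arrays on the hybridization controls or on the dap and thr poly-A controls. With 3 arrays against 3, the smallest exact permutation p of a single gene is 0.1, so p-values come from limma. The replicate numbers were shared by the lines, and nothing in the labels pairs same-numbered pools.

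The scripts were tested on simulated data with known changes made from these arrays. At gene level (6765 genes), 36%, 74%, 92% and 98% of changes of 1.41-, 2-, 4- and 8-fold were called, and 8.54% of the calls were unchanged genes. At probe set level (23999 probe sets), 12%, 38%, 86% and 92% of the same changes were called, and 8.8% of the calls were unchanged probe sets. Both shares of unchanged features were above the nominal 5%. The changed features were drawn from those with a mean above 4, and 6565 genes were left unchanged, against 2653 not called in these data. The matrix list with a simulated 2-fold shift was called in 20 of 20 simulations, and 0 of 580 unshifted lists were called. The simulated noise was independent between genes, so these simulations cannot show list calls that arise from correlated genes.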

Results

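The arrays compared OBGF400, a porcine olfactory bulb neuroblast line, with PK15, an established pig kidney line that the labels describe as non-neuronal and epithelial. The design used PK15 as a somatic background against which genes preferentially expressed by the neuroblast line could be found. Each line was represented by 3 arrays, and each array by a pool of RNA from several cultures. Over all tested probe sets, Pearson correlations across probe sets were 0.997 to 0.998 among OBGF400 arrays and 0.996 among PK15 arrays, against 0.860 to 0.865 between the lines. Probe sets are not independent replicates, so these values describe the arrays only.

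OBGF400 had higher signals of extracellular matrix genes and of single contractile, chemokine and neural genes such as ACTA2, CXCL14 and UCHL1. PK15 had higher signals of keratins, epithelial junction genes, HOX genes, cholesterol synthesis genes and cell division genes. Of 6765 genes, 1620 (23.95%) were higher and 2492 (36.84%) lower in OBGF400, and 2653 were not called (limma, adjusted p under 0.05). At least 2-fold differences were found for 933 genes higher and 1485 lower, and at least 8-fold differences for 312 higher and 386 lower. At probe set level 10060 of 23999 (41.92%) differed, 4846 higher and 5214 lower, and the number of probe sets differing between OBGF400 and PK15 was 19464 with median centring, 21558 with hybridization control scaling and 21593 with poly-A control scaling. The arrays of the lines did not overlap for 4528 genes (66.93%), where chance gives 10%. In both lines 1047 genes were at the floor of the table. The share of called genes that were higher in OBGF400 was 39.4% as deposited, 78.09% after scaling on the hybridization controls and 12.75% after scaling on the dap and thr poly-A controls. These scalings moved the median difference of all genes from -0.002 to 0.82 and -0.86, so small differences depend on the scaling. The lys and phe poly-A controls, at -0.29 and -0.11, were left out of the poly-A control scaling. The size of that scaling and the sign changes under it therefore rest on dap and thr alone. With 32 added to the linear values, there were 207 genes at least 8-fold higher in OBGF400 and 211 genes at least 8-fold lower in OBGF400. Camera called 11 of the 30 gene lists, and none with an estimated correlation, which gave the highest adjusted p of each of these 11 lists over its alternatives. Where no separate count is given, the counts adjusted over the list alone equalled those over all genes. Lists with a median difference within 0.1 of 0 took the sign of the control scaling used. Control scalings move genes at the floor in both lines by a constant, so calls of such genes carry no information on them.

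Where adding 32 to the linear values moved a gene's difference by over 1.5-fold, the difference with 32 added follows it after a slash. The genes with the largest rises in OBGF400 were MMP1, CXCL14, ACTG2, CHI3L1, ACTA2, CDH11, MMP2, COL15A1, THBS2, C1S, CNN1 and PRELP. MMP1, an interstitial collagenase, had a signal of 14.89 ± 0.13 in OBGF400 (SD, n = 3) and lay at the floor in PK15, a difference of 12.75 (9.70 with 32 added). CXCL14, a chemokine, was at 15.61 ± 0.03 against 3.03 ± 0.08 in PK15 (SD, n = 3), a difference of 12.59 (10.29 with 32 added). The smooth muscle actins ACTG2 and ACTA2 differed by 12.56 / 10.32 and 11.62 / 9.62, and the mesenchymal cadherin CDH11 by 11.61 / 8.57. The largest falls were those of ALDH1A1, RBP4, PERP, KRT8, SLPI, KRT18, EPCAM, KRT19, MAL2, WFDC2, CLDN4 and PDPN. ALDH1A1, a retinaldehyde dehydrogenase, was at 2.19 ± 0.07 in OBGF400 and 15.04 ± 0.10 in PK15 (SD, n = 3), a difference of -12.85 (-9.85 with 32 added). RBP4, the plasma retinol carrier, differed by -12.29 / -9.28 and the desmosome-associated PERP by -12.18 / -9.15. Adjusted p-values of these genes ranged from 2.2e-08 for PERP to 7.9e-05 for ACTA2. Many of them involve a level near the floor in 1 line, so their order among themselves carries no information.

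Matrix and mesenchymal genes were higher in OBGF400. Of 34 measured, 27 were higher, 1 lower and 6 not called, with a median difference of 4.83 (3.41 with 32 added), and adjusted over the list alone 28 were higher and 1 lower. Poly-A control scaling gave 23 higher and 8 lower. The gelatinase MMP2 (11.19 / 8.21), the matricellular genes THBS2 (10.76 / 7.78) and POSTN (10.04 / 7.09) and the pericyte and fibroblast receptor PDGFRB (9.88 / 7.65) were among them, while the calcium-binding S100A4 was lower (-1.99). The list was called by camera (adjusted p = 2.99e-11), with adjusted p = 0.0682 with an estimated correlation. Of 10 neural crest and epithelial-mesenchymal transition factors, 7 were higher and 1 lower, with a median of 3.65 (1.61 with 32 added), including CDH11, the homeobox factor PRRX1 (8.23 / 5.55) and the endothelin receptor EDNRA (5.37 / 2.70). This list had an adjusted p of 0.0018 and adjusted p = 0.164 with an estimated correlation. MSX1 was the lower member (-0.75), and after scaling on the hybridization controls it differed by 0.07. Of 19 smooth muscle, pericyte and contractile genes, 9 were higher, 1 lower and 9 not called, with a mean difference of 3.13 and a median of 0. The median became -0.85 under poly-A control scaling (9 higher, 10 lower) and 0.82 under hybridization control scaling (18 higher, 0 lower). The contractile regulator CNN1 was higher by 10.68 / 7.79. The myosin light chain MYL4 was lower (-1.05 / -0.39), with calls lost without OBGF400 replicate 1 (-0.80) or 3 (-1.06) or PK15 replicate 2 (-0.95) or 3 (-0.99). The contractile list had an adjusted p of 0.00249, and adjusted p = 0.176 with an estimated correlation. Vimentin (VIM), an intermediate filament common to mesenchymal cells, was at 15.14 ± 0.01 in OBGF400 and 15.04 ± 0.02 in PK15 (SD, n = 3), a difference of 0.11 that became -0.75 under poly-A control scaling.

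**Figure D1:**
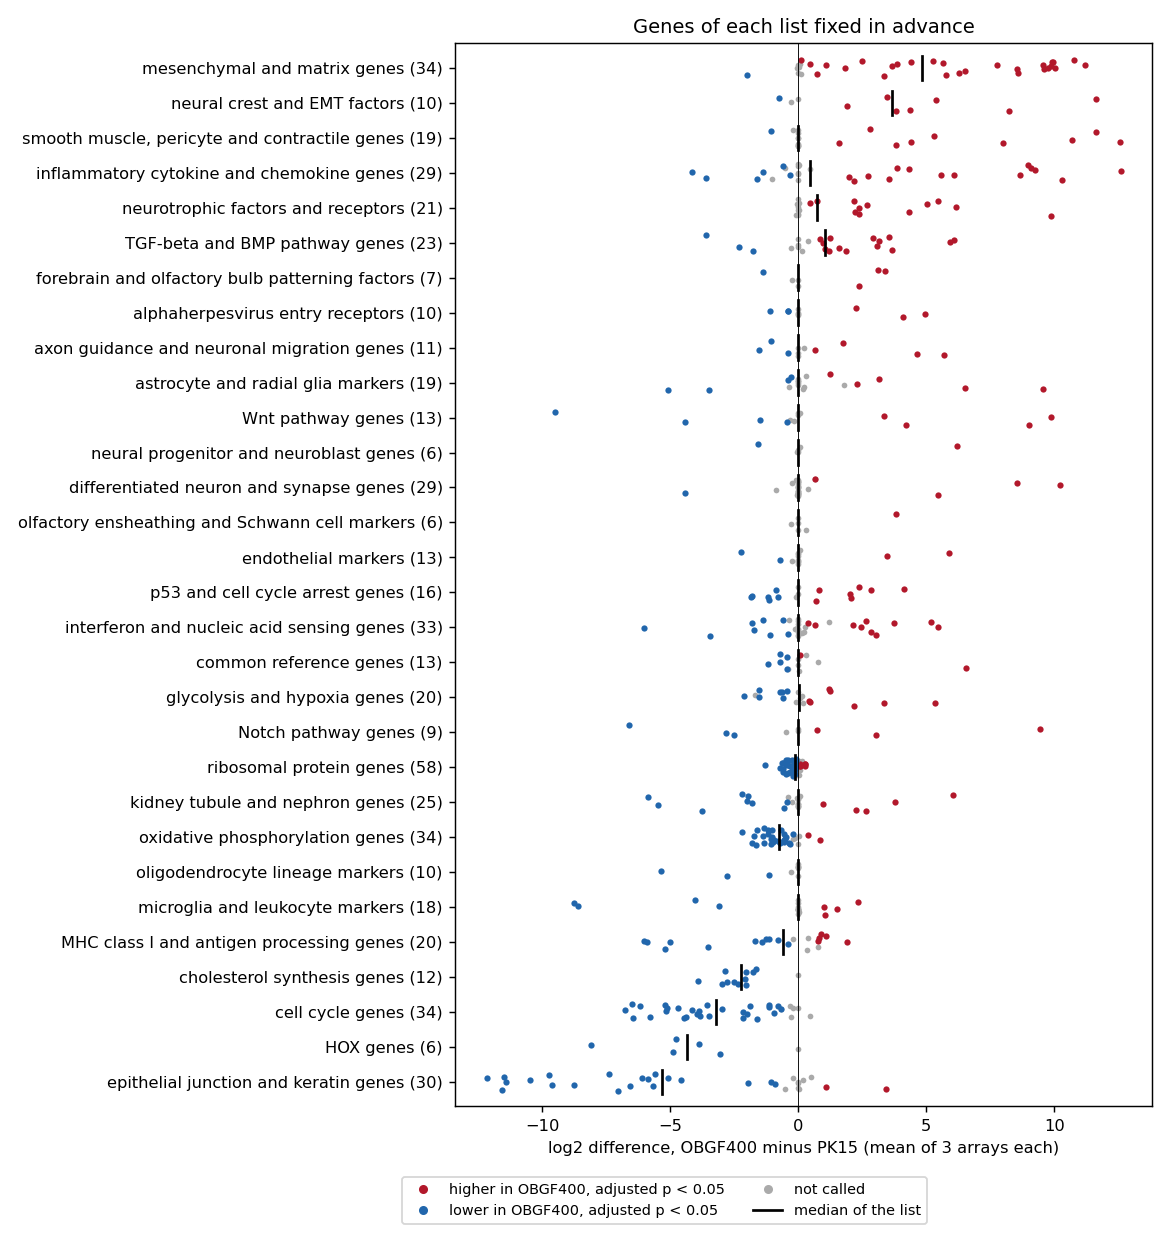
Log2 differences (OBGF400 minus PK15, x axis) of the genes of each list fixed in advance (y axis, measured genes in parentheses), with 1 point per gene coloured by its call and a black line at the list's median. Matrix genes lie to the right (27 of 34 higher) and epithelial genes to the left (20 of 30 lower), while lists with a median at 0 take the sign of the scaling used.

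Epithelial junction and keratin genes were lower in OBGF400. Of 30 measured, 20 were lower, 2 higher and 8 not called, with a median of -5.33 (-2.89 with 32 added), and adjusted over the list alone 21 were lower and 2 higher. Hybridization control scaling gave 9 epithelial genes higher and 18 lower. The simple-epithelium keratins KRT8 (-12.14 / -9.51) and KRT18 (-11.56 / -8.55), the epithelial adhesion molecule EPCAM (-11.48 / -8.58) and E-cadherin, CDH1 (-9.62 / -7.17), were among them, with KRT18 at the floor in OBGF400. CLDN12, a claudin, was higher in OBGF400 (3.42 / 1.49), as was CDS1 (1.09). The epithelial list had an adjusted p of 0.00025, and adjusted p = 0.115 with an estimated correlation. Of 25 kidney tubule and nephron genes, 5 were higher and 9 lower, against 16 higher and 7 lower under hybridization control scaling and 4 higher and 20 lower under poly-A control scaling. Camera did not call the kidney list (adjusted p = 0.796). The peptidase DPP4 (-5.87 / -3.15) and the nuclear receptor HNF4A (-5.47 / -3.80) were lower, and GATA3 (6.05 / 3.58) and GPX3 (3.76) were higher. Of 6 HOX genes, which carry positional identity along the body axis, 5 were lower in OBGF400 and 0 higher, with a median of -4.33 (-2.52 with 32 added). HOXA9 was at the floor in OBGF400 and at 10.26 ± 0.08 in PK15 (SD, n = 3), and HOXD8 differed by -4.89 / -3.93. The HOX list was called (adjusted p = 0.0421), with adjusted p = 0.433 with an estimated correlation, and was not called at a threshold of 0.01, after median centring (adjusted p = 0.0565) or without PK15 replicate 3 (adjusted p = 0.0512). Over the alternatives the adjusted p of HOX genes (list shift) ranged from 2.01e-05 to 0.433.

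Neuronal genes gave a mixed picture. Of 29 neuron and synapse genes, 4 were higher, 1 lower and 24 not called, 18 of them at the floor in both lines, and adjusted over the list alone 3 were higher and 1 lower. Hybridization control scaling gave 27 neuron genes higher and 1 lower, and poly-A control scaling 3 higher and 24 lower. These counts include genes at the floor in both lines, whose sign was set by the scaling. The ubiquitin hydrolase UCHL1, abundant in neurons, was at 12.34 ± 0.07 in OBGF400 (SD, n = 3) and at the floor in PK15, a difference of 10.21 / 7.16. The surface glycoprotein THY1 (8.53 / 5.91) and the dendritic microtubule protein MAP2 (5.44 / 3.63) were also higher, and DDC, an enzyme of dopamine synthesis, was lower (-4.41 / -2.26). Of 6 measured neural progenitor and neuroblast genes, the adhesion molecule NCAM1 was higher (8.87 ± 0.32 against 2.68 ± 0.47, SD, n = 3) and STMN1 lower (-1.58). Of 7 forebrain patterning factors, MEIS2 (3.37), NR2F1 (3.13 / 1.01) and TSHZ1 (2.38) were higher and ETV5 lower (-1.39). Only 1 of 2 MEIS2, 1 of 3 TSHZ1 and 1 of 2 ETV5 probe sets was called. The ETV5 call was lost without OBGF400 replicate 1 (-1.35) or 3 (-1.26) or PK15 replicate 3 (-1.41). Of 11 axon guidance and migration genes, 4 were higher, with EFNB2 (5.68 / 3.07) and PLXNA2 (4.63), and 3 were lower. The camera test called none of these 4 lists, with adjusted p-values of 0.257 for neuron genes, 0.742 for progenitor genes, 0.257 for forebrain factors and 0.352 for axon guidance. NES, DCX, TUBB3, SOX2 and PAX6, common neural markers, have no named probe set in the annotation used here and were not analysed here.

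Among 19 astrocyte and radial glia genes, 5 were higher and 4 lower (camera adjusted p = 0.257). The matrix glycoprotein TNC (9.54 / 7.44) and the gap junction gene GJA1 (6.51) were higher. The astrocyte filament gene GFAP was lower (2.64 ± 0.30 against 7.74 ± 0.27, SD, n = 3), by the 1 of its 4 probe sets that was called. S100B was at 2.51 ± 0.41 against the floor in PK15 and was not called (adjusted p = 0.31). Of 10 oligodendrocyte genes, 3 were lower and 0 higher, against 2 lower and 7 higher under hybridization control scaling and 10 lower and 0 higher under poly-A control scaling, and adjusted over the list alone 2 were lower. MBP, a myelin protein gene, differed by -5.36 / -2.82. Of 6 ensheathing and Schwann cell genes, the neuropeptide NPY was higher (3.82 / 1.52). Camera called neither list (adjusted p = 0.666 and 0.507). Among 18 leukocyte genes, 4 were higher and 4 lower. Hybridization control scaling gave 14 leukocyte genes higher and 4 lower, and poly-A control scaling 2 higher and 14 lower. Those lower as deposited included LAPTM5 (-8.75 / -5.77), AIF1 (-8.58 / -5.56) and the myeloid factor SPI1 (-4.02 / -1.70), with AIF1 at 10.72 ± 0.11 in PK15 (SD, n = 3). The mean of the list was -1.03 and fry gave a downward direction, whereas camera gave an upward one without a call (adjusted p = 0.796). Of 13 endothelial genes, 2 were higher, with ERG at 5.90 / 3.17, and 2 were lower (adjusted p = 0.553).

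**Figure D2:**
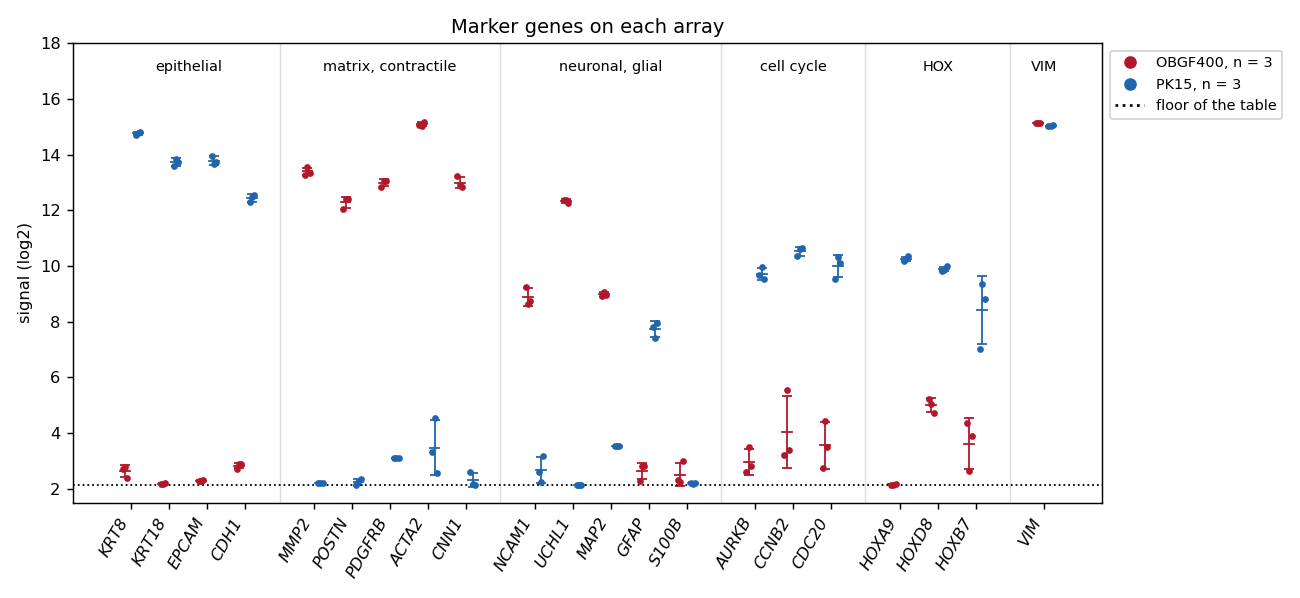
Signal (log2, y axis) of selected genes (x axis) on each array, with points for the 3 OBGF400 (red) and 3 PK15 (blue) arrays, and lines for the mean and the SD. Keratins, cell cycle and HOX genes are lower in OBGF400, matrix and contractile genes and NCAM1, UCHL1 and MAP2 are higher, and VIM differs by 0.11, which becomes -0.75 under poly-A control scaling.

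Cell cycle genes were lower in OBGF400. Of 34 measured, 28 were lower, 0 higher and 6 not called, with a median of -3.23, and adjusted over the list alone 29 were lower and 1 higher. Under hybridization control scaling 23 cell cycle genes were lower and 5 higher. The mitotic kinase AURKB (2.96 ± 0.47 against 9.72 ± 0.22, SD, n = 3), the cyclin CCNB2 (4.05 ± 1.30 against 10.53 ± 0.16) and the mitotic exit gene CDC20 (3.56 ± 0.84 against 10.00 ± 0.41) had the largest falls. The cell cycle list had an adjusted p of 0.000153, and adjusted p = 0.605 with an estimated correlation. The p53 and arrest genes went both ways, with 7 higher and 6 lower of 16. BTG2, an antiproliferative gene, was higher (4.14 / 3.39) and the quinone oxidoreductase TP53I3 lower (-1.86 / -1.002). This list was not called by camera (adjusted p = 0.553) and was the one list that fry did not call (adjusted p = 0.0533).

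Cholesterol synthesis genes were lower in OBGF400, with 11 of 12 lower and 0 higher and a median of -2.22. NSDHL differed by -3.89 / -3.28, the squalene epoxidase SQLE by -2.98 and the sterol sensor partner INSIG1 by -2.85. The cholesterol list had an adjusted p of 0.00025, and adjusted p = 0.115 with an estimated correlation. Of 34 oxidative phosphorylation genes, 28 were lower and 2 higher, with a median of -0.76, which became 0.06 under hybridization control scaling, with 10 genes higher and 10 lower. Adjusted over the list alone, 29 were lower and 2 higher. The complex I genes NDUFA1 (-2.21) and NDUFB8 (-1.80) and the complex III gene UQCRB (-1.73) fell most. The oxidative phosphorylation list had an adjusted p of 0.00025, and adjusted p = 0.449 with an estimated correlation, and was not called under poly-A control scaling. Of 58 ribosomal protein genes, 30 were lower and 6 higher, with a median of -0.14, which became 0.69 under hybridization control scaling (52 higher, 1 lower) and -0.99 under poly-A control scaling. Adjusted over the list alone, 31 ribosomal genes were lower and 6 higher. Camera did not call them (adjusted p = 0.223), with a downward direction although the list's shift against other genes was 0.01. Signals of the 28S rRNA probe sets were higher in OBGF400 by 1.07 and those of the 5′ actin probe sets by 0.62, while the actin 3′ probe set differed by 0.05. Of 20 glycolysis and hypoxia genes, 7 were higher and 7 lower (adjusted p = 0.553). The glucose transporter SLC2A3 was higher (5.34), as was adrenomedullin, ADM (3.36), and PFKL was lower (-2.12). VEGFA was higher (2.18) by the probe set used, but its called probe sets disagreed in sign.

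Of 29 inflammatory cytokine and chemokine genes, 14 were higher, 6 lower and 9 not called, with a median of 0.46 (0.07 with 32 added) that became -0.39 under poly-A control scaling. Beside CXCL14, the monocyte chemokine CCL2 (10.28 / 7.75) and the prostaglandin synthase PTGS2 (9.25 / 7.24) were higher, and CXCL2 (-4.15 / -3.50) and TGFB1 (-3.61 / -2.91) were lower. The cytokine list had an adjusted p of 0.00388, and adjusted p = 0.426 with an estimated correlation. Of 21 neurotrophic factors and receptors, 12 were higher and 0 lower, with a median of 0.73 that became -0.13 with 10 higher and 9 lower under poly-A control scaling, and adjusted over the list alone 11 were higher. They included the neurotrophin BDNF (8.75 ± 0.66, SD, n = 3, against 2.60 on each PK15 array, a difference of 6.16 / 3.61) and IGF1 (5.47 / 3.14). The neurotrophic list had an adjusted p of 0.00102, and adjusted p = 0.173 with an estimated correlation. Of 23 TGF-beta and BMP pathway genes, 14 were higher and 3 lower, with a median of 1.03, which became 0.18 with 9 higher and 9 lower under poly-A control scaling. The ligand TGFB2 (6.08 / 3.41) and the activin antagonist FST (5.92 / 3.20) were higher, and the activin subunit INHBA was lower (-2.32 / -1.53). The TGF-beta list had an adjusted p of 0.00105, and adjusted p = 0.173 with an estimated correlation.

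The remaining lists held called genes in both directions and were not called by camera. Of 9 Notch genes, 3 were higher and 3 lower (adjusted p = 0.796), with the effector HEY2 at 9.45 / 6.52, the glycosyltransferase LFNG at -6.60 / -4.17 and the ligand JAG1 at -2.83. Of 13 Wnt genes, 4 were higher and 4 lower (adjusted p = 0.553), with the secreted antagonists SFRP1 at 9.87 / 7.52 and DKK3 at 9.02 / 7.96 and the receptor FZD6 at -9.51 / -6.77. Of 33 interferon and nucleic acid sensing genes, 10 were higher and 8 lower (adjusted p = 0.257), against 26 and 5 under hybridization control scaling and 8 and 23 under poly-A control scaling. The list held the interferon receptor subunit IFNAR2 at 5.45 / 3.23 and the exonuclease ISG20 at -6.02 / -3.41. Of 20 MHC and antigen processing genes, 5 were higher and 11 lower (adjusted p = 0.376), with a median of -0.59. Under hybridization control scaling the median became 0.23, with 10 genes higher and 8 lower, and poly-A control scaling gave 1 higher and 14 lower. The class II genes SLA-DRA (-6.03 / -3.20) and SLA-DQA1 (-5.89 / -3.27) and the immunoproteasome gene PSMB8 (-5.21 / -3.34) were lower, and the class I gene SLA-2 was higher (1.91). Of 10 alphaherpesvirus entry genes, 3 were higher and 3 lower (adjusted p = 0.507). The syndecan SDC2 (4.95) and the nonmuscle myosins MYH10 (4.09 / 2.19) and MYH9 (2.25) were higher. EXT1 (-0.40) and SDC1 (-0.38) were lower by the probe set used, while another probe set of each was called higher, both turned positive under hybridization control scaling, and without OBGF400 replicate 3 neither was called (-0.42 and -0.34). Of 13 reference genes, 2 were higher and 5 lower (adjusted p = 0.796). The transferrin receptor TFRC differed by 6.54 / 4.19 and HPRT1 by -1.18. The mean of that list was 0.29, while its median was -0.01 and camera and fry gave a downward direction.

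**Figure D3:**
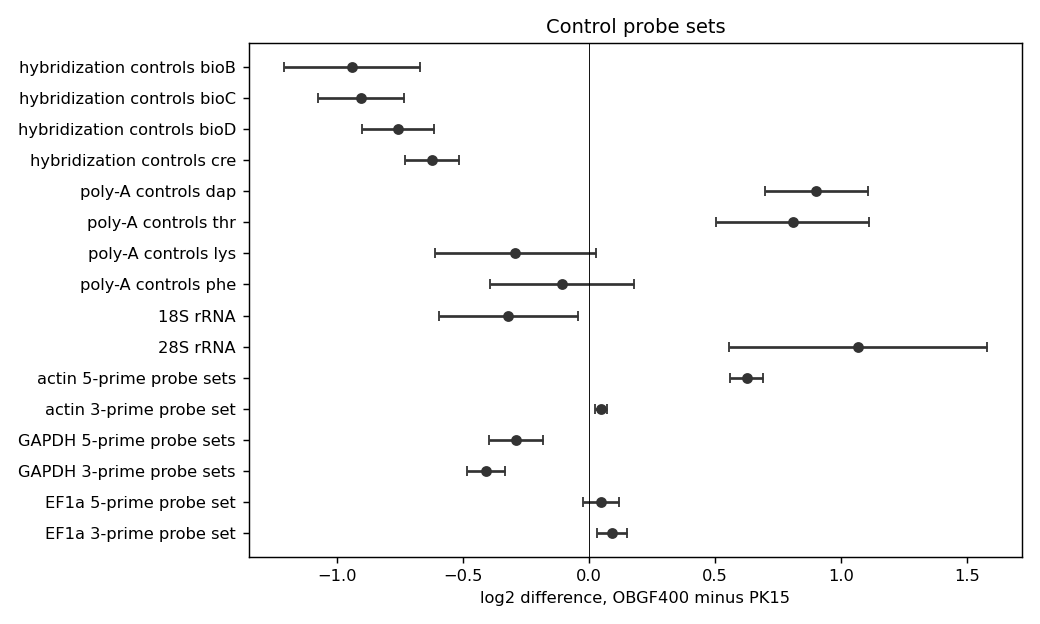
Log2 difference (OBGF400 minus PK15, x axis) of control probe sets (y axis), with points at the difference of the means of 3 arrays per line and bars for the root of the summed squared SDs of both lines. Hybridization controls lie at -0.94 to -0.62, the dap and thr poly-A controls at 0.90 and 0.81, and 28S rRNA at 1.07.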

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

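The tests of control probe sets between the lines were chosen only after the results were seen. These probe sets were left out of the tests of genes, and each result here is a signal outside the main measurement that was higher in OBGF400 than in PK15 by over 0.5, with no overlap between the arrays. The poly-A controls, bacterial transcripts that are added to the RNA before labelling, were higher by 0.90 for dap and 0.81 for thr. The 28S rRNA probe sets were higher by 1.07, the 5′ actin probe sets by 0.62, the middle probe set of a second actin group by 3.65 and its 5′ probe set by 0.80.

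The hybridization controls, which are added after labelling, moved the other way, by -0.94 for bioB, -0.91 for bioC, -0.76 for bioD and -0.62 for cre. The lys and phe poly-A controls overlapped between the lines (-0.29 and -0.11). The shift of dap and thr exceeded that of the hybridization controls by 1.68, each set moving by more than its spread between arrays, which argues against 1 scale factor between the arrays of the lines. Different amounts of added control RNA, or of labelled product, stay open as contributions. A common change of all poly-A controls would also have raised lys and phe, which did not rise. This argues against such a change as the whole cause. No biological explanation was tested for added transcripts. Line and hybridization batch cannot be told apart here.

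The actin 3′ minus 5′ difference was lower in OBGF400 by -0.58 and the GAPDH one by -0.12, while the EF1a one overlapped between the lines (0.04).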

How the results depend on the processing

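The control scalings and the leaving out of unvarying probe sets were chosen after seeing the data, and the other alternatives before. The 7 counts of genes and probe sets stayed within 1.5 times their values under quantile normalization, both dim filters, the variance and weight options, the mean of a gene's probe sets, a threshold of 0.01, the replicate block, each left-out array and the exclusion of unvarying probe sets. Genes removed by a filter, and lists with fewer than 5 genes left, gave no value. With 32 added, there were 207 genes at least 8-fold higher in OBGF400 and 211 genes at least 8-fold lower in OBGF400, since the offset shrinks differences near the floor.

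All 11 called lists lost their call with an estimated correlation, at unchanged shifts against other genes of 3.97 for neural crest, 5.06 for matrix, 3.33 for contractile, -4.45 for epithelial, -3.94 for HOX, -2.83 for cell cycle, 2.83 for cytokine, 2.28 for neurotrophic, 1.48 for TGF-beta, -2.06 for cholesterol and -0.61 for oxidative phosphorylation genes. The estimated correlations of the neural crest (-0.080), epithelial (-0.00996) and cholesterol (-0.056) lists lay below the preset 0.01. This argues against a higher correlation between genes as the cause of their losses. The other called lists had estimates above it, from 0.0125 for matrix to 0.534 for cell cycle genes. The cause of the losses was not tested further, so a lost call is not by itself a sign of correlated genes. The shift of HOX genes (list shift) was -3.94, and the list also lost its call under median centring, at 0.01 and with the replicate block. Its shift ranged from -4.12 to -3.81 over left-out arrays, and the call ended without PK15 replicate 3 (-3.87, adjusted p = 0.0512). The other 10 called lists kept their calls under each left-out array.

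With the replicate block, 3782 genes were called, 3705 of them among the 4112 called without it. Deviations of same-numbered pools correlated by 0.0392, 0.00614 and 0.0185. OBGF400 replicates 1 and 3 correlated best with the PK15 pool of the same number, and replicate 2 with PK15 replicate 3 (0.0281). Values this small on 3 pools per line neither show nor exclude a pairing, and the labels give none.

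The number of probe sets differing between OBGF400 and PK15 was 19464 with median centring, 21558 with hybridization control scaling and 21593 with poly-A control scaling. Hybridization control scaling gave 4487 genes higher in OBGF400 and 1259 genes lower in OBGF400, with 1909 genes at least 2-fold higher in OBGF400 and 753 genes at least 2-fold lower in OBGF400. Poly-A control scaling gave 763 and 5219 genes, 558 and 2899 at 2-fold, and 611 genes at least 8-fold lower in OBGF400. These scalings shift probe sets that do not vary by a constant, which then pass the test. The oxidative phosphorylation list (-0.61) was not called under poly-A scaling. Genes that reversed under hybridization control scaling were LRP8 (0.43), CLU (0.41), MSX1 (0.074), FLT1 (0.13), EXT1 (0.43), SDC1 (0.44), RPL8 (0.13), RPL14 (0.21), PGK1 (0.10) and SDHA (0.10). Under poly-A scaling RBPJ (-0.13), COX7C (-0.48), RPS23 (-0.59), RPS19 (-0.59), RPS12 (-0.61), RPL4 (-0.77), S100B (-0.55) and VIM (-0.75) reversed. With the mean of a gene's probe sets EXT1 (0.062), SDC1 (0.16), NDUFS3 (-1.26) and RPS12 (-0.052) reversed, as did RPL4 (-0.019) with quantile normalization. Apart from the shifts named, the cause was not tested. Low signals limit the table, since levels near the floor have no order.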

Other observations

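The gene families, the genes measured in both lines, the scaling test of cell cycle genes, the test of neuron genes at the floor and the second test of mixed cells were chosen only after the results were seen. Collagen genes were higher in OBGF400 for 9 of 15 measured and lower for 0, with a median of 4.42. This family was picked after the rise of matrix genes was seen and shares members such as COL1A2 and COL6A3 with that list, so it is no separate evidence of it. Of 58 mitochondrial ribosomal protein genes, 48 were lower, 27 of them at least 2-fold, and 3 higher, with a median of -0.96 that moved to -0.13 under hybridization control scaling and -1.81 under poly-A control scaling, so the size of its fall rests on the scaling. Scaling whole arrays leaves the shift against other genes unchanged. The camera adjusted p was 3.55e-07 for the values as deposited, and adjusted p = 0.31 with an estimated correlation. Camera p-values can change with scaling at an unchanged shift, as for the oxidative phosphorylation list under poly-A control scaling. Camera was not run on the families under the control scalings, and their p-values were adjusted over the families alone. Of 33 proteasome genes, 24 were lower and 3 higher, with a median of -0.50 that became 0.32 under hybridization control scaling (camera adjusted p = 0.00205, and adjusted p = 0.317 with an estimated correlation).

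Among genes measured well above the floor in both lines, a selection also made after the values were seen, the muscle tropomyosin TPM2 was 253-fold higher in OBGF400 (15.49 ± 0.09 against 7.50 ± 0.14, SD, n = 3). The actin-bundling FSCN1 was higher by 6.19 / 5.51, the calcineurin regulator RCAN1 by 5.38 and the chemokine CXCL8 by 5.59. The selenium carrier SELENOP was 94.5-fold lower (8.24 ± 0.05 against 14.80 ± 0.33, SD, n = 3), the kinetochore gene NUF2 differed by -5.31 / -4.60 and calreticulin, CALR, by -5.02. Of the called probe sets with 1 gene symbol, 44.0% of 5217 were higher in OBGF400, against 52.7% of 4843 without one, so the split of named genes does not stand for all probe sets.

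The fall of cell cycle genes was weighed against array scaling and against a single pool. Under quantile, median, hybridization control and poly-A control scaling the smallest fall of the list's median was -2.41, which argues against scaling as the whole cause. The lowest PK15 pool lay 2.27 above the highest OBGF400 pool in the list's median level, with OBGF400 pools at 6.40, 7.65 and 7.07 and PK15 pools at 9.92, 10.27 and 10.15, which argues against 1 pool with few dividing cells. Differences in growth, density or medium between the cultures stay open and were not tested.

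At the floor in both lines were 18 of 29 neuron genes (62.1%) and 20 of 41 endothelial, leukocyte and oligodendrocyte genes (48.8%; two-sided Fisher's exact p = 0.3336 between these sets), and without neural tissue on the array probe sets that give no signal anywhere cannot be told apart from silent genes. Mesenchymal cells mixed into the OBGF400 cultures in a varying share were weighed on the 33 matrix and contractile genes called over 2-fold higher. Their median level was 12.82, and they spread between pools 2.14 times as much as other called genes of like level. A varying share would give such a ratio. The comparison genes also included those called under 2-fold, which pass only with a small SD, so this choice can raise the ratio too. A second test, added after that result was seen, went the other way, since the genes highest in the same pool were at most 39.39% (13 of 33 in each of 2 pools and 7 in the other, exact 95% interval, added after this share was seen, 22.9% to 57.9%). The median deviations of these genes from their means were -0.00146, -0.00463 and -0.0402 in the 3 pools, near 0 over genes that went both ways. The interval takes the largest of 3 shares and treats 33 genes on the same 3 pools as independent, so it decides nothing. Neither test decides, so a varying share stays open. A constant share and a mesenchymal character of the line itself were not tested, and THY1, TNC and PDGFRB of the matrix list also belong to the neuron, astrocyte and neurotrophic lists.

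The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split with as large a result for each count. It gave 10060 probe sets, 1620 and 2492 genes higher and lower, 933 and 1485 at 2-fold and 312 and 386 at 8-fold, and the highest count in the other splits was 0 for each. Each other split has arrays of both lines in each group, so differences between the lines add to the spread within groups. Counts of 0 there are therefore no baseline for chance. The real split called 11 lists by camera, and the highest of the other splits called 7. Each other split holds the lines in unequal numbers per group and so keeps part of their difference. The 7 lists are therefore no count of false calls.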
